A study of Drosophila melanogaster with 2 samples.

How the data were processed

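Peak lists from 2 biological replicates of 1 group were analysed. Per the labels, embryos of 0 to 24 hours carried CG4730 fused to eGFP, chromatin was sonicated to 200 to 800 bp, and the immunoprecipitation used an antibody to GFP. The control library was not analysed here. Per the labels, coordinates are on dm6. The peak caller, the aligner and their versions were not given in the sources used here.

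For each replicate the authors deposited a ranked list and a list thresholded by the irreproducible discovery rate (IDR), and for the pooled replicates also a conservative pair. The deposited signal value of each peak has no stated unit. The deposited score is a capped transform of the global IDR (in the pooled ranked list it equalled a multiple of the negative log2 of that rate, rounded down to a whole number and capped at 1000, for 143037 of 143047 peaks), and the ranked lists the authors deposited also give −log10 of that rate. All kept peaks passed a global IDR of 0.01, the rate planned as a stricter setting, so the stronger part of the peaks by signal was used in its place. Rates below 0.01 were not tried. The 2 pooled ranked lists hold 16 columns with values of the compared inputs, which have no names and were not used. Intervals rest on numbers of peaks or genes, not on the spread between the 2 replicates. Wilson intervals at the 95% level and floors of 3 counts cover counting error only, and shares in a replicate's own set can lie outside them.

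The pooled thresholded set was the main set. The gene annotation was Ensembl's for this assembly, with 18277 genes on 7 arms, 13968 of them protein-coding, and the sequence was NCBI's. Peak ends were checked to lie within the lengths of the arms. Promoters reached 500 bp to either side of a start. Feature shares were compared with 1000 random placements on the same arm, overlaps with 1000 circular shifts, and median signals by 100000 permutations. Arms, 27 gene lists and 24 motifs were compared by Fisher's exact test with Benjamini-Hochberg adjustment within each family. Arms were also compared with their share of sequence length by an exact binomial test, adjusted in the same way. Windows of 50 bp to each side of the summit were set against windows of the same width centred 500 bp to each side. The 8-mers were ranked on 2L, 2R and X and tested on the other arms. Tests were two-sided at an adjusted threshold of 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used with seed 1.

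Groups, main tests, lists, motifs and the rule for named genes were set before the data were examined. The rule took the 20 strongest pooled peaks present in both replicates' sets by the nearest start, up to 4 members per list with the strongest promoter peak, CG4730, and the 5 strongest peaks over 5000 bp from a start. The base composition, summit position, shared promoter and left-out peak analyses, the matching of 15 list symbols by synonym, the shuffled windows, the gene-order shift, the motif test on the weaker 1776 peaks, the feature test on the 300 strongest peaks and the list test without ribosomal protein genes among the genes compared were chosen after the data were seen.

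Statistics were tested on simulated data. A planted overlap of 60% in 1000 peaks came back as 62.8%, a planted motif share of 15% in 1000 windows as 15.4%, and Fisher's test found 100% of 20 planted gene lists. The base-pair shift of the peaks found 0 of the same 20 lists and the gene-order shift 100%, with 1.67% of 60 lists without an effect passing an unadjusted threshold. An earlier form of the base-pair shift, which added a pseudocount, gave false calls for short lists and was replaced after the data had been seen. The simulated tests were completed after a first pass over the data, whose results were discarded. Left-out peaks were redefined by the unrounded IDR after their overlap had been seen.

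Alternatives were the conservative set, the stronger peaks, each replicate's own set, other windows and overlaps, other backgrounds for motifs and other null placements.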

Results

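Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where the protein encoded by CG4730 lay on the genome of Drosophila melanogaster embryos aged 0 to 24 hours. The protein carried a green fluorescent protein tag (eGFP), and an antibody against GFP pulled down the bound DNA. The labels give 1 group with 2 biological replicates, so no test between groups was possible and each comparison describes where the peaks lay. The authors' pooled set held 3571 peaks, of which 3551 lay on the 7 chromosome arms and 20 on unplaced scaffolds. The own sets of replicate 1 and replicate 2 held 2309 and 2434 peaks. The read depth behind them was not given in the sources used here. Signal values below are the authors' own per-peak values, whose unit was not stated, and they serve to rank and describe peaks. Unless called pooled, values of named peaks are means over the replicates' own sets. All coordinates are on dm6 and count from 1.

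The strongest peak of the pooled set lay on X from 2703706 to 2704057, with its summit 40 bp upstream of the start of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. Its signal was 1123 ± 2.32 over the replicates' own sets (mean ± SD, n = 2), where the SD is the spread between those 2 lists. Next came peaks 97 bp upstream of CG14100 (FBgn0036889; 3L, 19590462 to 19590788), at 1023 ± 38.2 (SD, n = 2), and 103 bp upstream of CG7601 (FBgn0027583; 3R, 29736694 to 29737005), at 924 ± 7.11 (SD, n = 2). Of the 20 strongest peaks found in both replicates, 14 had their summit within 500 bp of a transcription start and 9 lay near starts of 2 or more genes.

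Several of these peaks lay at genes for mitochondrial ribosomal proteins: mRpL41 (2R, 15217592 to 15217892; 876 ± 10.9), the region between Art3 and mRpS10 (3R, 15229380 to 15229685; 720 ± 18.4), the region of CenG1A and mRpS23 (2L, 13835315 to 13835598; 626 ± 4.90) and mRpL23 (3L, 2373470 to 2373746; 570 ± 18.3), each as mean ± SD with n = 2. A peak inside ph-p, a Polycomb group gene, 498 bp upstream of the nearest of its annotated starts, reached 817 ± 14.0 (SD, n = 2; X, 2137200 to 2137525). A peak in an intron of Adf1, a transcription factor gene, 800 bp downstream of its nearest start, reached 741 ± 98.7 (SD, n = 2; 2R, 6662912 to 6663230). The peak shared by Chro, which encodes Chromator, and Ssl1 reached 651 ± 45.1 (SD, n = 2; 3L, 22878751 to 22879046). Others lay near Tcs5 and CHMP2B (782 ± 93.4), eIF6, a factor of large ribosomal subunit formation, and asRNA:CR45928 (668 ± 78.1), PNPase, an RNA-degrading enzyme (661 ± 17.2), CG5611 and Mtl (619 ± 88.2) and CG18549 (573 ± 17.1), again with n = 2. The remaining members were nearest to CG11050, CG32772 and HmgZ, each in an intron, and to lncRNA:CR45643 and CG13323, in intergenic sequence.

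**Figure D1:**
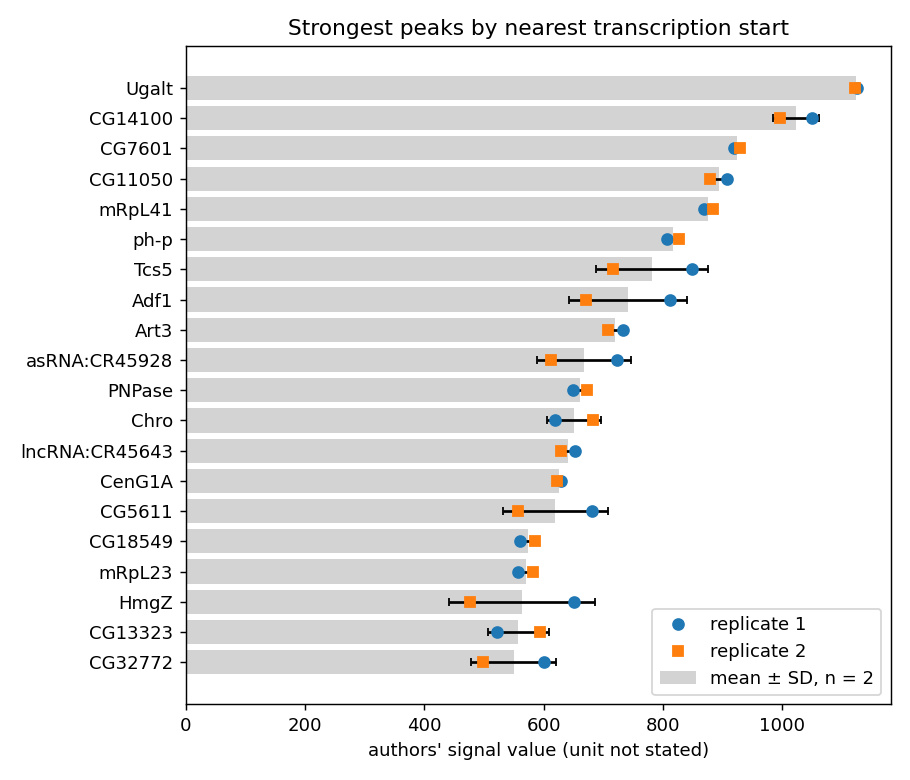
Signal of the 20 strongest peaks, named by the gene with the nearest transcription start. Bars give the mean of the replicates' own sets with the SD (n = 2), points give each replicate, and the x axis is the authors' signal value, which runs from 549 for CG32772 to 1123 for Ugalt.

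The replicates' own sets were compared by overlap. Of the 2271 peaks of replicate 1 on the arms, 1753 (77.2%) overlapped a peak of replicate 2 by at least 1 bp, against a mean of 1.01% after circular shifts along each arm (two-sided permutation p = 0.002, the smallest that 1000 shifts give). All 300 strongest pooled peaks overlapped a peak of both replicates, whereas 822 of the 3551 overlapped a peak of neither. The median signal was 174 for the 1744 pooled peaks found in both and 71.2 for those found in neither. Across the 1753 shared peaks Spearman's correlation between the replicates' signals was 0.819. This value is across peaks, which are not independent replicates.

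Promoters held more summits than random placement gave. Within 500 bp of an annotated start lay 1546 of 3551 summits (43.5%, Wilson 95% interval 41.9 to 45.2%), against 13.5% after random placement on the same arm (adjusted permutation p = 0.0035). Coding exons held 51 summits (1.44% against 13.7%), 3' UTRs 29 (0.817% against 4.44%) and intergenic sequence 528 (14.9% against 27.3%), each with adjusted permutation p = 0.0035. Coding exons held 0.105 times the random share, and 0.0289 and 0.0603 times in the own sets of replicates 1 and 2. Introns held 1348 summits (38.0% against 39.4%, adjusted permutation p = 0.0956). The intron share was above random placement, at 1.13 times with adjusted permutation p = 0.0028, when promoters were limited to 100 bp, and the intergenic call was then lost, at 29.2% against 29.7% (adjusted permutation p = 0.535). With the stronger 1775 peaks it was below, at 34.8% against 39.4% (adjusted permutation p = 0.0028), as it was in each replicate's own set. Of the 624 peaks more than 5000 bp from any start, the strongest were nearest to CG13323 (558 ± 50.8; 2R, 13035212 to 13035477), CG16753 (412 ± 51.3; 3L, 3060672 to 3060927), CG46321 (371 ± 35.2; 2R, 10219948 to 10220223), lncRNA:CR45695 (357 ± 122; 2L, 1638616 to 1638948) and lncRNA:CR44603 (288 ± 0.964; 2L, 1632703 to 1632961), as mean ± SD with n = 2.

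Peaks at promoters had higher signal than the others. The median was 127 for the 1546 promoter peaks and 99.6 for the 2005 others, a difference of 27.5 (two-sided permutation p = 2e-05, the smallest that 100000 resamples give). Within replicate 1's own set the difference was 15.8, and within replicate 2's it was 11.95. Peaks of a set are not replicates, so the p-value describes these peaks only.

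Chromosome X held 697 of the 3551 peaks, an odds ratio of 1.31 against its share of protein-coding genes (Fisher's exact test, adjusted p = 2.7e-07). Arm 3L also held more, with 791 peaks and an odds ratio of 1.17 (Fisher's exact test, adjusted p = 0.00084). Arm 2R held fewer, with 622 peaks and an odds ratio of 0.828 (Fisher's exact test, adjusted p = 0.000234), as did 3R, with 802 and 0.899 (Fisher's exact test, adjusted p = 0.0206). Chromosome 4 held 2 peaks for 80 coding genes (odds ratio 0.0978, Fisher's exact test, adjusted p = 1.05e-05). No peak lay on Y, which allows a share of up to 0.0845% (Fisher's exact test, adjusted p = 0.0115). Replicate 1's own set held 1 peak on Y, which ended that call (Fisher's exact test, adjusted p = 0.24), and replicate 2's own set held 5 peaks on chromosome 4 (odds ratio 0.358, and 0.153 in replicate 1's). With the stronger 1775 peaks 3L and Y did not pass (odds ratios 1.13 and 0, Fisher's exact test, adjusted p = 0.0651 and 0.119). By sequence length 2R and 3R did not (odds ratios 0.943 and 0.959, exact binomial test, adjusted p = 0.217 and 0.302).

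Genes for cytoplasmic ribosomal proteins, the protein part of the translation machinery, carried promoter peaks most often among the lists. A summit lay within 500 bp of a start for 49 of 93 (52.7%, Wilson 95% interval 42.6 to 62.5%) and for 13.4% of other coding genes, an odds ratio of 7.18 (Fisher's exact test, adjusted p = 1.09e-17). The odds ratio was 4.42 in replicate 1's own set (30 of 93), 4.20 with the stronger 1775 peaks and 20.5 with a window of 100 bp. From 500 to 100 bp the count fell from 49 to 41 for ribosomal protein genes. For the 13875 other coding genes it fell from 1862 to 513, so summit position enters the value of 20.5. The 49 genes rested on 49 distinct peaks. The strongest were at RpL23A (281 ± 32.8; 3L, 1668650 to 1668880), RpS27 (181 ± 3.43; 3R, 25247411 to 25247625), RpS28b (142 ± 0.957; X, 9554497 to 9554674) and RpL34b (141 ± 11.5; 3R, 9401331 to 9401435), as mean ± SD with n = 2. Their median pooled signal was 109, below the 127 of all promoter peaks, and 2 of the 49 peaks were among the 300 strongest. Shifting the peaks along the arms in base pairs gave adjusted permutation p = 0.0539. That test found none of the lists planted in simulated data. Its unadjusted permutation p was 0.002, the smallest that the shifts give. After adjustment over 27 lists, a list alone at that smallest value could not pass the threshold. Shifting in gene order gave adjusted permutation p = 0.0135.

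Mitochondrial ribosomal protein genes carried a peak in 18 of 73 cases (24.7%), an odds ratio of 2.07 (Fisher's exact test, adjusted p = 0.0384). That call did not hold with replicate 2's own set alone (odds ratio 1.86, Fisher's exact test, adjusted p = 0.157), with the stronger 1775 peaks (2.10, 0.12), with windows of 100 bp (1.79, 0.581) or 1 kb (1.79, 0.147), or with left-out peaks restored (2.02, 0.062). It was also lost under the shifts in gene order (1.77 times the shifted count, adjusted permutation p = 0.108) and in base pairs (2.17 times, adjusted permutation p = 0.931).

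The lists of cuticle protein genes and of odorant and gustatory receptor genes were lower. A promoter peak lay at 1 of 97 cuticle protein genes, Cpr30B, whose peak was in neither replicate's own set, and at 0 of 119 odorant and gustatory receptor genes, which allows up to 2.52%. The adjusted p-values of Fisher's exact test were 0.000101 and 4.74e-07. The other lists that were lower held replication-dependent histone, tRNA and snoRNA genes. There, 0 of 111, 8 of 295 and 13 of 257 genes had a promoter peak (Fisher's exact test, adjusted p = 1.17e-06, 4.74e-07 and 0.00315). The tRNA and snoRNA odds ratios were 0.213 and 0.410, and 0.0758 and 0.267 in replicate 1's own set. Where genes have several like copies, reads that fit several of them may be removed before peak calling. How such reads were treated was not given in the sources used here. The histone genes lie in a cluster, and their call was lost under the gene-order shift, with the count still 0 (adjusted permutation p = 0.0809). With a window of 100 bp only the tRNA and snoRNA lists of these 5 passed, and the base-pair shift ended all 5 calls, at 0 to 0.538 times the shifted count. With a window of 1 kb the snoRNA call ended and its direction turned, with 38 of 257 and an odds ratio of 1.03 (Fisher's exact test, adjusted p = 0.927), and the tRNA and cuticle odds ratios were 0.405 and 0.216, against 0.0652 for cuticle genes with 500 bp.

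The other 20 lists did not pass the threshold with the pooled set. Among regulators of patterning, no peak lay at the 8 Hox genes, 2 of 25 segmentation genes had one (bcd and ptc, the latter in neither replicate's own set), as did 4 of 27 dorsoventral genes, with tin at 205 ± 38.2 and cact at 106 ± 8.17 (SD, n = 2), and 4 of 19 Notch pathway genes, with numb at 134 ± 26.6 (SD, n = 2). Among tissue lists, the counts were 1 of 30 for the nervous system (elav, an RNA-binding protein of neurons, 258 ± 1.26, SD, n = 2), 3 of 25 for muscle (sls, 154 ± 20.7, SD, n = 2), 3 of 12 for gut (bowl, 220 ± 19.8, SD, n = 2), 0 of 17 for blood and fat body, 1 of 18 for trachea and epidermis (trh) and 3 of 21 for germline and piRNA genes. Polycomb and trithorax group genes had 6 of 26, among them brm, a chromatin remodelling ATPase (381 ± 0.142), and E(z), a histone methyltransferase (157 ± 6.93), and insulator and promoter-binding proteins had 4 of 16, among them BEAF-32 (84.1 ± 8.06) and M1BP (70.5 ± 10.3), with SD and n = 2. In replicate 2's own set this list passed, with 6 of 16 and an odds ratio of 5.15 against 2.11 in the pooled set (Fisher's exact test, adjusted p = 0.0159). Cell cycle and replication genes had 7 of 34, ecdysone response genes 2 of 16, heat shock genes 5 of 22 (Hsp27, 344 ± 24.3, SD, n = 2), translation initiation factors 8 of 44, tRNA synthetases 7 of 33, respiratory complex I 5 of 40, proteasome subunits 5 of 48 and snRNA genes 5 of 32.

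**Figure D2:**
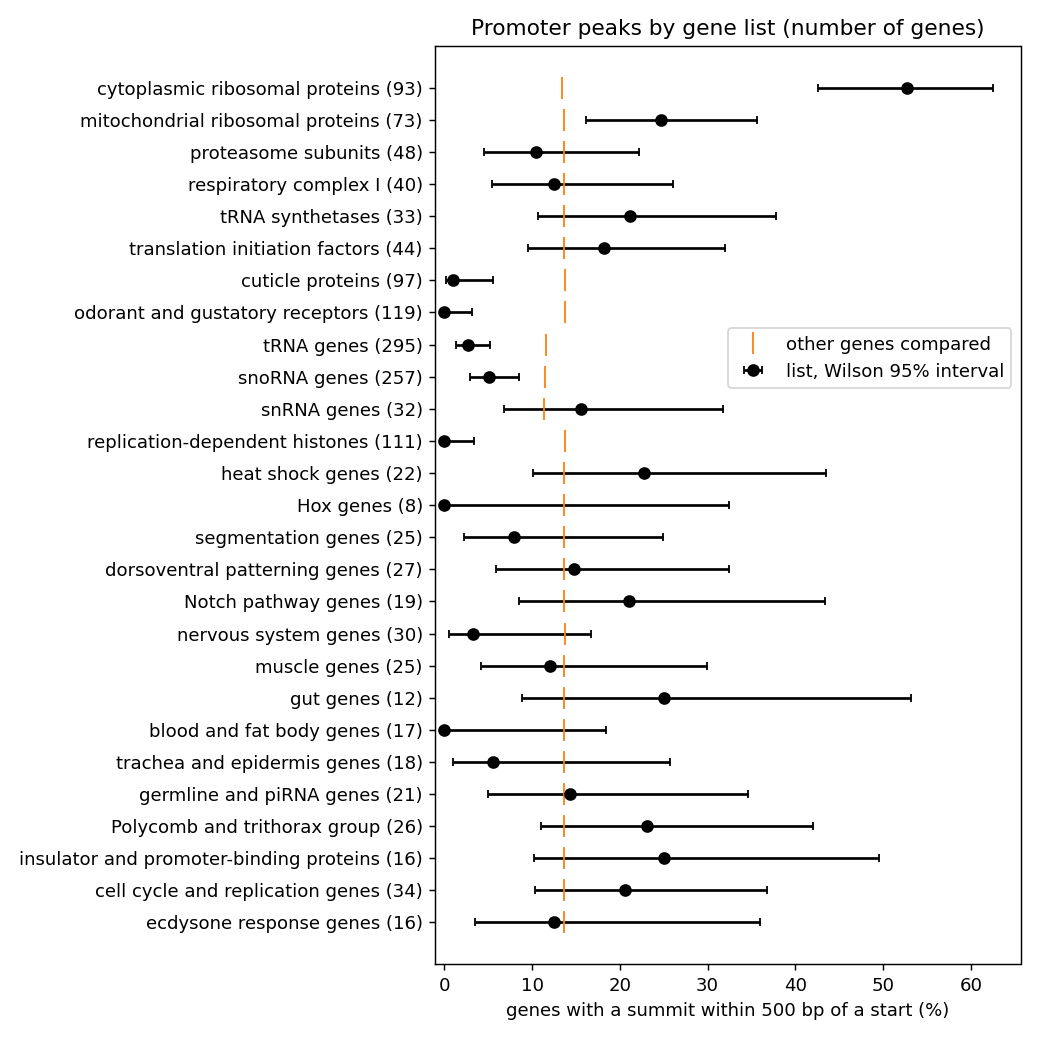
Percentage of genes of each list with a summit within 500 bp of a transcription start, with Wilson 95% intervals, and the same percentage among the other genes compared. Cytoplasmic ribosomal protein genes lie at 52.7%, and odorant and gustatory receptor genes at 0 of 119.

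Bases around the strongest summits were mostly A or T. At the 300 strongest, 71.0 ± 8.28% of bases within 50 bp of the summit were A or T (SD over summits), against 55.9% in flanks centred 500 bp away. The difference was 15.1 points at these and 5.56 points at the 1776 weaker peaks (permutation p = 0.0002 for each, the smallest that 10000 draws give). This comparison was chosen after the peaks had been seen.

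**Figure D3:**
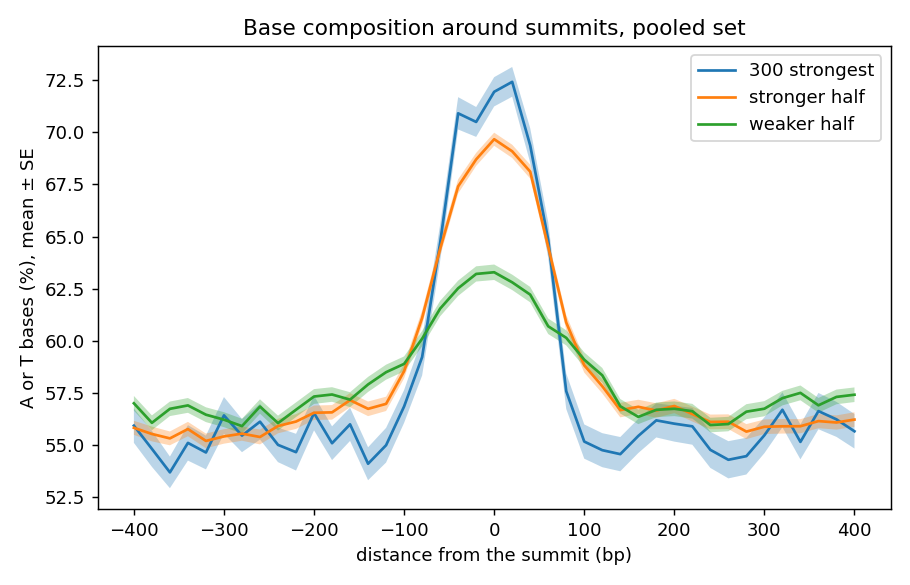
Percentage of A or T bases by distance from the summit, as mean ± SE over peaks, for the 300 strongest, the 1775 stronger and the 1776 weaker peaks of the pooled set. The line of the 300 strongest reaches 72.4% at 20 bp and lies at 55.9% at 400 bp upstream in genome order.

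Motifs of known DNA-binding proteins and core promoters were compared between summits and the same flanks. Of 24 motifs, 11 were more frequent and 10 less frequent within 50 bp of summits. The TATA box sequence was in 21.6% of summit windows and 10.8% of flanks (odds ratio 2.27, Fisher's exact test, adjusted p = 1.2e-46), and the homeodomain sequence in 10.3% and 5.94% (odds ratio 1.81, Fisher's exact test, adjusted p = 2.17e-14). Against shuffled copies of the same windows with unchanged dinucleotide counts, the TATA box excess was not found (odds ratio 1.04, Fisher's exact test, adjusted p = 0.651) and the homeodomain sequence was rarer at summits (odds ratio 0.737, Fisher's exact test, adjusted p = 0.000155). The DRE (0.873% of windows), the CTCF core (0.648%) and the ZIPIC sequence (0.648%) were more frequent than in flanks, with odds ratios of 3.47, 6.61 and 5.78, and than in shuffled copies, with 15.6, 7.71 and 3.85. The counts behind them were 31, 23 and 23 of 3551 windows. Against promoters without a peak, the DRE did not pass (odds ratio 1.30, Fisher's exact test, adjusted p = 0.372). Nor did the CTCF core, whose odds ratio there was 5.01 from 5 of 1442 windows against 2 of 2884 (Fisher's exact test, adjusted p = 0.0774). The ZIPIC, TATA box and homeodomain sequences did pass there, with odds ratios of 3.81, 1.60 and 1.76 (Fisher's exact test, adjusted p = 0.00309, 1.16e-07 and 2.55e-06). Over all settings the CTCF core odds ratio ran from 2.85 with windows of 100 bp to each side of the summit to 20.1 with the weaker 1776 peaks. In replicate 1's own set ZIPIC did not (odds ratio 2.87, Fisher's exact test, adjusted p = 0.0518), and in replicate 2's the DRE odds ratio was 5.22. Lower at summits than in flanks were the CACA repeat (odds ratio 0.243) and GAGA (0.324), with 0.143 and 0.194 in replicate 1's own set, and both were higher than in shuffled copies.

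The 8-mer ranked first on arms 2L, 2R and X was TATATTAA, found in 64 of 1595 summit windows on the other arms (4.01%) and in 1.07% of flanks (odds ratio 3.88, Fisher's exact test, p = 7.28e-11). In the replicates' own sets other AT-rich sequences came first, ATATAAAA in replicate 1 (odds ratio 2.24) and TAAAATAA in replicate 2 (odds ratio 3.20). Ranked against shuffled copies, the first was AGATGGCG, in 21 of 1595 windows (1.32%) and in 0.188% of copies (odds ratio 7.08, Fisher's exact test, p = 2.68e-06).

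The tagged gene itself, CG4730 (FBgn0039355; 3R, 25677072 to 25678682), had no thresholded peak within 1000 bp in any of the 4 sets. The strongest peak within 10000 bp lay on 3R from 25680628 to 25680872, 96 bp upstream of Idh3g, a gene of an isocitrate dehydrogenase subunit, and near the start of CG4743, with a signal of 353 ± 71.1 (SD, n = 2) and rank 67 in the pooled set. Before the threshold, the pooled ranked list held 6 peaks within 1000 bp of CG4730, the strongest at pooled signal 59.2 and rank 4697. On the same pooled scale the peak near Idh3g had a signal of 711.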

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

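The tests in this part on left-out peaks, base composition and ribosomal protein promoters were chosen after those patterns were seen. For the comparison of ribosomal protein genes with 3 further lists and the reading of the repeat test, the result was also known. The design has 1 group, so no biological explanation was tested.

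Peaks that passed the IDR threshold but were missing from the thresholded sets numbered 112 for the pooled set, 85 for the conservative set, 115 for replicate 1 and 66 for replicate 2. Of the 112 pooled ones, 28 lay on unplaced scaffolds, against 20 of the 3571 kept pooled peaks. The repeat share of those 28 was not read. Of the 84 pooled ones on the arms, 74 lay on 3R and 2L, and 56 lay in runs of 2 or more neighbours. The strongest was nearest to cbt on 2L (480916 to 481262). Its pooled signal was 1991, rank 3 in the pooled ranked list, against a pooled signal of 2235 for the kept peak at Ugalt. Repeats as the source of most on the arms are argued against by the median share of repeat-masked bases. It was 19.1% in these 84 (bootstrap 95% interval 14.0 to 23.4%), where 50% was needed, and 18.8% in kept peaks. The share in kept peaks also made the opposing bound of 10%, set before the result, too low. The 84 formed 47 runs of neighbouring peaks, so the interval may be too narrow. A fixed list of excluded regions may be the source: 0.265% of the 378 left-out peaks (1 peak) overlapped a kept peak of any set, whereas 92.8% of kept peaks overlapped a kept peak of another set. Such a list would give 0, and left-out peaks were redefined after an overlap had been seen, so this stays open.

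Peaks on chromosome Y were present before the threshold, with 628 in the pooled ranked list, 504 in the conservative one, 481 in replicate 1 and 69 in replicate 2, although the pooled thresholded set held none there and replicate 1's held 1.

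The strongest summits lay in an AT-rich block. At the 300 strongest, 71.0 ± 8.28% of bases were A or T (SD over 300 summits) against 55.9% in flanks, a difference of 15.1 points (permutation p = 0.0002, the smallest that 10000 draws give). Promoter base composition as the whole cause is argued against by the 189 of these summits at coding promoters, which exceeded promoters without a peak at the same distance by 10.9 points. Preferred recovery of AT-rich DNA stays open: 17.0% of the 7959 coding promoters with an equally AT-rich window carried a peak, against 13.7% of all coding genes, but with 1911 bound genes that share could not exceed 24.0%, so it decides nothing. Signal was higher at AT-rich summits (Spearman's correlation 0.343 across pooled peaks, 0.242 and 0.257 in the replicates' own sets). This restates the pattern over all peaks, so it cannot decide for or against such a preference.

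Ribosomal protein promoters differed from that block. Their median AT content was 52.5%, lower than at the 300 strongest summits by 19.8 points (bootstrap 95% interval 16.8 to 22.8). Only 2 of the 49 ribosomal protein summits were among those 300, so peak strength also differed. Against the 1497 other promoter summits the gap was smaller, with means of 54.3 ± 9.03% and 66.9 ± 10.1% (SD over summits). Summit position differed too. Of the 49 ribosomal protein genes with a summit within 500 bp of a start, 41 had one within 100 bp. Among other coding genes, 513 of 1862 did. Unspecific signal shared with translation initiation factor, heat shock and snRNA genes was weighed through those lists together, whose odds ratio of 1.75 (95% interval 0.987 to 2.96) lay below that of the ribosomal protein genes against all annotated genes, 8.83 (5.74 to 13.6). Transcription was not measured, so a wider effect of high transcription stays open, and the control library was not analysed here.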

How the results depend on the processing

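Alternatives chosen after the data were seen are the shuffled windows, the weaker 1776 peaks for motifs, the 300 strongest peaks for features, the restored left-out peaks, the lists without ribosomal protein genes among the genes compared, the gene-order shift, and all those for the AT difference, the upstream position and shared promoters. Promoter enrichment, the overlap of the replicates, the promoter to distal difference, the enrichment of the first k-mer (though its sequence changed with the set), the AT difference, the upstream position and the shared promoter result kept their direction and side of the threshold in every alternative run. The stronger part of the pooled set held 1785 peaks, and leaving out a replicate gave 2309 to 2434. Spearman's correlation of the replicates' signals across shared peaks was 0.839 for summits within 100 bp. Lists higher numbered 2, and 1 with stronger peaks, with windows of 100 bp or 1 kb, with left-out peaks restored and with the gene-order shift. Replicate 2's own set also gave 2, but there the insulator and promoter-binding list passed (odds ratio 5.15, Fisher's exact test, adjusted p = 0.0159) and the mitochondrial ribosomal list did not. The ribosomal protein odds ratio of 7.18 became 4.42 to 6.61 without a replicate, 4.20 with stronger peaks and 20.5 with the 100 bp window. The base-pair shift left 0 lists higher and 0 lower, and the ribosomal protein list at 4.36 times (adjusted permutation p = 0.0539). The unadjusted permutation p of that list was 0.002, the smallest that the shifts give. After adjustment over 27 lists, a list alone at that smallest value could not pass the threshold, so its loss decides nothing. That shift found no planted list in simulation. The simulation planted only lists with more peaks, and had fewer peaks and shifts than the data. It therefore cannot tell how much the losses of the lower lists and of the mitochondrial ribosomal list say. Lists lower numbered 5, and 2 with the 100 bp window. Motifs higher numbered 11, between 7 and 10 without a replicate, and 5 against promoters without a peak. Motifs lower numbered 10, and 5 against shuffled windows. Within 10 kb of CG4730 lay 4 peaks, 3 in the conservative set and 2 in each replicate's own set, and the ranked list held 6 within 1 kb. Reversed with a 100 bp promoter were 5' UTR (1.16) and intron (1.13) shares, where the intergenic call was also lost (0.983), and with a 1 kb window the snoRNA odds ratio (1.03). Against promoters without a peak, odds ratios reversed for the BEAF-32 site (0.976), Ohler motif 1 (0.215), GATA (0.965) and the Twist E-box (1.05). Against shuffled windows they reversed for E-box CAGCTG (2.03), GAGA (2.56), Ibf (0.762), Pho (1.02), GATA (0.745), homeodomain (0.737), Adf1 (1.56) and the CACA repeat (5.03). Past the threshold in neither setting, 32 further values changed direction or came to 1.00. With the stronger peaks these were other exons (0.974), respiratory complex I (1.18), snRNA (0.424), gut (0.967) and cell cycle genes (0.664) and Ohler motif 6 (1.00). With the 100 bp window they were proteasome (2.21), complex I (1.28), segmentation (1.01), muscle (1.01), dorsoventral (0.931), Polycomb and trithorax (0.968), ecdysone (1.62), gut (0) and germline genes (0). Without a replicate the odds ratios ranged from 0.570 to 1.061 for proteasome, 1.22 to 1.94 for complex I, 0.364 to 1.498 for snRNA, 0.829 to 1.71 for gut, 0.901 to 0.960 for germline and 0.608 to 1.22 for ecdysone genes, and from 0.857 to 1.00 for Ohler motif 6. The conservative set changed germline genes (0.721) and Ohler motif 6 (0.923), promoters without a peak Ohler motif 6 (0.499) and Pita (0.662), shuffled windows Ohler motif 6 (1.00), sequence length arm 2L (1.0601) and the base-pair shift dorsoventral genes (0.734). The cause was not tested for any of these. Of the tested values of single features, arms, lists and motifs, 447 kept their direction and side of the threshold, 62 lost and 9 gained a call, and 47 changed direction or came to 1.00, 15 of them with a call in either setting. No paired analysis was possible because there is 1 group.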

Other observations

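The tests of summit position and of shared promoters were chosen after the peaks had been seen. Summits lay upstream of coding starts more often than downstream: 1039 were within 300 bp upstream and 178 within 300 bp downstream, a ratio of 5.84 (exact binomial p = 3.16e-148, across peaks). Of the 300 strongest peaks, 158 (52.7%, Wilson 95% interval 47.0 to 58.2%) lay within 300 bp upstream of a coding start, against 3.33% of randomly placed summits.

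A hypothesis was that peaks prefer promoter regions shared by divergent coding genes. Of 1850 regions between divergent starts within 500 bp, 444 (24.0%, Wilson 95% interval 22.1 to 26.0%) held a summit, against 5.94% of 10268 single promoter regions, an odds ratio of 4.9998 (Fisher's exact test, p = 1.13e-109). A shared region has 2 starts, which alone would raise the share. If both starts acted independently at the single rate, 11.5% would be expected, a comparison added after the result was seen. The excess is consistent with the hypothesis, but open chromatin or high expression of such gene pairs was not measured and may account for it.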
